A study of Homo sapiens with 18 samples.

How the data were processed

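RNA-seq libraries from a pair of human non-small cell lung cancer cell lines, H1299 and A549, were analysed. The cells had been transfected for 48 h with 30 nM of a control siRNA (siControl) or of a SMARTpool, a mixture of siRNAs against the same transcript, directed at YAP (gene YAP1, siYAP) or at TAZ (gene WWTR1, siTAZ). They were kept without serum for the final 18 h. Each of the 6 combinations of line and siRNA had 3 libraries made from poly(A) RNA, 18 in all. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. H1299 was grown in RPMI-1640 and A549 in DMEM, and the lines were deposited as separate tables, so line, medium and experiment go together.

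Reads were trimmed with cutadapt and aligned with STAR 2.4.2a, the build was GRCh38 and DESeq2 was used, per the submitters' processing notes. The tool that assigned reads to genes, its annotation and its use of strand are not given in the sources used here. The authors deposited raw read counts per gene symbol, 1 table per line, and each table lists genes with at least 6 counts in some library. The deposited signal columns are normalized counts, and each equals the raw count times 1 constant per library to within a relative error of 1e-06. The deposited log2 columns are named as regularized log values in H1299 and as batch-adjusted values in A549. The authors' log2 fold changes, p-values and adjusted p-values are in the same tables. Refitting the counts with DESeq2 gave the log2 fold changes of the authors' deposited table to within 0.001 for 100% of H1299 genes with no batch term, and for 99.995% of A549 genes with the replicate number as a batch term. Apart from these checks, only the raw counts were analysed.

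The H1299 libraries held 16.8 to 20.8 M assigned reads (median 18.8 M, highest over lowest 1.24) and the A549 libraries 10.7 to 45.0 M (median 20.7 M, ratio 4.21). Replicates of a group were no copies of each other, with chi-square per degree of freedom over genes of 5.97 to 27.5. The tables list 18978 genes for H1299 and 20335 for A549. Symbols were matched to GENCODE release 29 (GRCh38), which held 97.9% of them in each table. Gene identifiers, biotypes, positions and overlaps were taken from it.

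Each line was fitted on its own over its 9 libraries, so that the 3 groups shared the estimate of the spread. Genes were filtered with filterByExpr by group (15775 tested in H1299, 16008 in A549), library sizes were scaled by TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p below 0.05. Differences between the lines were tested as interaction terms in a joint fit of all 18 libraries over the 15816 genes that passed the filter among the 17094 in both tables. Log2 fold changes are given ± the standard error of the fit, and CPM (counts per M assigned reads, scaled by TMM) as mean ± SD, with n = 3 libraries per group throughout.

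The labels number the replicates of every group 1 to 3. Deviations of log CPM (prior count 2) from the group means were correlated between libraries of different groups of a line. Libraries with the same number had correlations of 0.108 to 0.383 in H1299 (median 0.221) and of 0.384 to 0.729 in A549 (median 0.528), each above 0.1. Libraries with different numbers had correlations of -0.324 to 0.160 and of -0.550 to 0.279. The numbers were therefore taken to pair the libraries, and fits with the replicate number as a block are given where they changed a list call or moved a count of called genes by over 1.5 times. In H1299 the block called no fewer members of any list in either direction. What the number stands for is not given there.

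The designs, the alternatives, the 24 gene lists and the rule for the genes named were fixed before the data were examined. The rule took YAP1 and WWTR1. For each knockdown against control it took the 10 protein-coding genes with the largest change in each direction, among those with an adjusted p below 0.05, a mean of at least 5 CPM and all knockdown libraries on one side of all control libraries. For siYAP against siTAZ and for differences between lines it took 5 in each direction, the latter without the condition on sides. For each gene list it took the 3 members with the smallest adjusted p, and any member of the YAP/TAZ target signature that passed. In A549, where the fit without the block called few genes, the same rule was applied to the fit with the block after seeing the data, with the same direction in each of the 3 same-numbered pairs in place of the condition on sides.

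Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, on lists with at least 3 members tested. P-values were adjusted over the 94 list tests of the 4 contrasts with control together, and over those of the siYAP against siTAZ contrasts as a second family. The test was repeated with the correlation estimated per list, and with fry, which tests whether a list's genes move in one direction on balance and compares the list with no other genes. Members are counted per direction over all genes tested and adjusted over the list alone.

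The alternatives were DESeq2 size factors in place of TMM, no filter and a filter of at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate block, fits of the compared groups alone, a 1.5-fold minimum, an adjusted p below 0.01, and each library left out in turn. Correlations between the knockdowns of a line, which share 3 control libraries, were set beside 20 simulations of unchanged groups and controls. Overlaps were set beside that of independent lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for words in annotated 3′ UTRs and for the plots.

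Each fit had its own simulated data, drawn for the genes and library sizes of siYAP and siControl. Genes were changed by known folds (over 3 simulations, 201 by 1.5-fold, 201 by 2-fold and 198 by 4-fold). In the simulated H1299 comparison, 53.2% of genes changed 1.5-fold, 79.6% changed 2-fold and 96.0% changed 4-fold were called, and 5.58% of calls were false. With the block they were 71.6%, 84.6% and 97.0% (7.33% of calls false). In the simulated A549 comparison the shares were 25.4%, 64.7% and 85.4% without the block (5.66% of calls false) and 77.1%, 89.1% and 99.5% with it (6.51%). For the simulated difference between lines in the siYAP effect they were 11.9%, 54.2% and 81.3% (4.55%), and with the block 48.8%, 77.1% and 90.4% (6.49%). With independent genes, camera called a list of 30 shifted 1.5-fold and 0 of 20 unshifted. Correlated lists were untested.

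Because strand use in counting is not given, genes that overlap another annotated gene are uncertain, on the same strand or as antisense partners. Of the 88 genes named outside the lists, 10 overlap a gene on the same strand and 26 on the opposite strand. They are marked in the text.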

Results

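Transcripts were measured by RNA-seq of poly(A) RNA after siRNA knockdown of either of a pair of paralogous transcriptional coactivators, YAP and TAZ, which bind TEAD transcription factors and are restrained by the kinases of the Hippo pathway. H1299 is a human lung carcinoma line derived from a lymph node metastasis that lacks p53, and A549 is a human lung adenocarcinoma line with intact p53. In each line, cells had received a control siRNA, an siRNA pool against YAP or an siRNA pool against TAZ, with 3 libraries per group and 18 libraries in all. Libraries are named by siRNA and replicate (siYAP 1). Assigned reads per library ranged from 16.8 to 20.8 M in H1299 and from 10.7 to 45 M in A549. Adjusted p-values are those of edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment unless another test is named.

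Knockdown was examined first. In H1299, YAP1 (chromosome 11, 102110461 to 102233423, GRCh38) stood at 84.0, 84.4 and 78.1 CPM in the controls and at 12.7, 19.6 and 11.7 CPM under siYAP, which is 15.5%, 23.9% and 14.3% of the control mean. WWTR1, which encodes TAZ (chromosome 3, 149517235 to 149736714), stood at 266.8, 278.2 and 230.0 CPM in the H1299 controls and at 36.0, 82.6 and 28.8 CPM under siTAZ, or 13.9%, 32.0% and 11.2%. In A549, YAP1 went from 59.4, 56.9 and 58.8 CPM in the controls to 16.9, 15.4 and 19.4 CPM under siYAP, which left 28.9%, 26.3% and 33.3%. A549 WWTR1 went from 173.9, 179.8 and 177.9 CPM to 70.4, 51.1 and 51.8 CPM under siTAZ, which left 39.7%, 28.9% and 29.2%. All 4 reductions passed the test: YAP1 fell by 2.48 ± 0.15 (log2, SE) in H1299 (adjusted p = 2.6e-06) and by 1.76 ± 0.09 in A549 (adjusted p = 9.1e-05). WWTR1 fell by 2.38 ± 0.28 in H1299 (adjusted p = 0.000334) and by 1.62 ± 0.12 in A549 (adjusted p = 0.00218). The other paralog was 180.6 ± 19.4 CPM for WWTR1 under H1299 siYAP (70% of control) and 100.5 ± 4.9 CPM for YAP1 under H1299 siTAZ (122% of control). Those log2 changes of -0.51 ± 0.26 and 0.30 ± 0.13 did not pass without the block (adjusted p = 0.204 and 0.117) and did with it (adjusted p = 0.0398 and 0.0316). In A549 the other paralog did not pass in either fit: WWTR1 under siYAP had a log2 change of -0.16 ± 0.12 (adjusted p = 1, with the block 0.0846) and YAP1 under siTAZ 0.04 ± 0.09 (adjusted p = 1, with the block 0.703). Antisense transcripts are annotated at both genes, and reads from them cannot be told apart here.

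**Figure D1:**
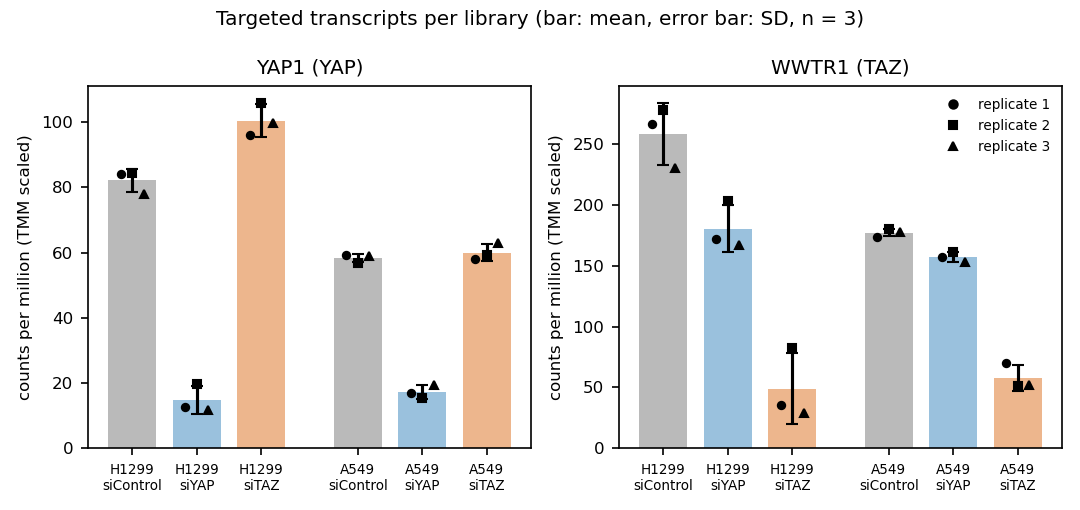
CPM of YAP1 (left) and WWTR1 (right) in each library by line and siRNA, with symbols for the replicate numbers, bars for the group mean and error bars for the SD (n = 3). The targeted transcript lies below all controls of its line in every library, and its highest remaining level is 82.6 CPM, for WWTR1 in H1299 siTAZ replicate 2.

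Principal components of log CPM separated the H1299 libraries by siRNA, with the controls, the siYAP and the siTAZ libraries apart on the first 2 components (35.4% and 22.5% of the variance). In A549, the first component (48.0%) separated replicate 3 of each group from replicates 1 and 2, and the second held 12.1%.

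**Figure D2:**
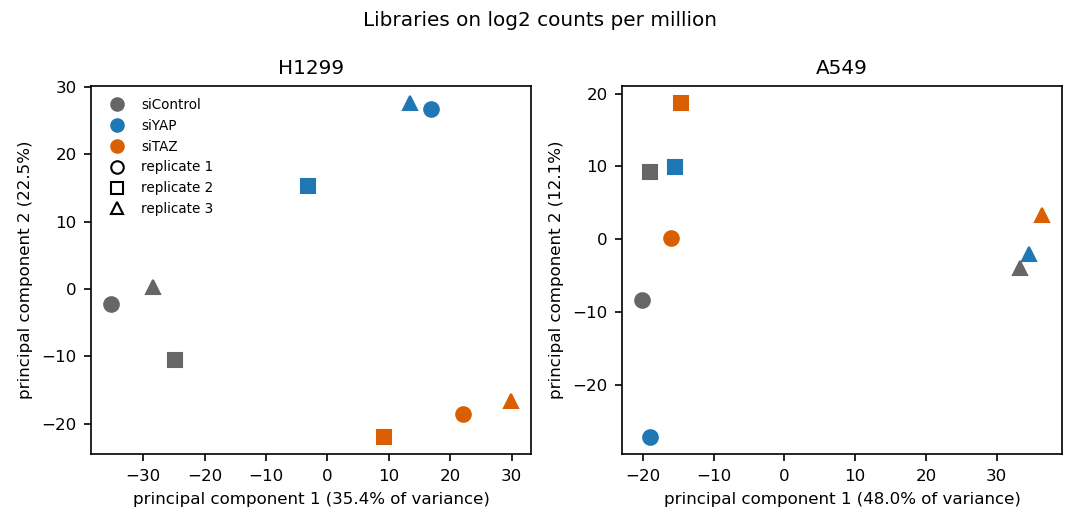
Libraries of H1299 (left) and A549 (right) on the first and second principal components of log2 CPM, with colours for the siRNA and symbols for the replicate number. H1299 libraries group by siRNA, and the 3 A549 libraries of replicate 3 stand apart from the other 6 on the first component.

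To determine which transcripts depend on YAP in H1299, siYAP was compared with siControl. CYR61, a classical YAP and TAZ target, fell from 430.0 ± 148 to 164.3 ± 9.4 CPM (log2 change -1.38 ± 0.23, adjusted p = 0.00219). CTGF, another such target, fell from 105.9 ± 18.5 to 62.7 ± 5.7 CPM (-0.75 ± 0.13, adjusted p = 0.00295). SREBF2, which drives cholesterol synthesis, fell from 585.0 ± 39.6 to 251.7 ± 56.3 CPM (-1.21 ± 0.13, adjusted p = 0.000297). VGF, a secreted peptide precursor, rose from 242.4 ± 29.8 to 634.9 ± 79.5 CPM (1.4 ± 0.13, adjusted p = 7.49e-05). Of 15775 genes tested, 1244 were higher and 1381 lower (16.6%), and 337 of these changed at least 2-fold.

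Among protein-coding genes with a mean of at least 5 CPM and all siYAP libraries on one side of all controls, the largest decreases in H1299 siYAP apart from YAP1 were in PLOD2, a collagen lysyl hydroxylase (from 101 ± 16 to 30.9 ± 7.5 CPM, log2 change -1.70 ± 0.16, adjusted p = 0.000158), and ARL6IP1, a protein of the endoplasmic reticulum (from 325.2 ± 87.2 to 105.7 ± 20.4 CPM, -1.61 ± 0.17, adjusted p = 0.000249). OSTM1, a lysosomal protein, fell from 136.9 to 46.3 CPM (-1.56 ± 0.16, adjusted p = 0.000242). COMMD8 (-1.5 ± 0.20), ATF3 (-1.44 ± 0.30), CENPA, the centromeric histone (-1.42 ± 0.19), KITLG, the KIT ligand (-1.34 ± 0.33), and PMAIP1, pro-apoptotic NOXA (-1.31 ± 0.13), were with CYR61 the rest of the 10 largest among them, with adjusted p from 0.000205 to 0.0159. The largest increases among such genes were in SERPINB7, a protease inhibitor (from 3.08 ± 0.68 to 11.7 ± 5.4 CPM, 1.93 ± 0.31, adjusted p = 0.00204), PTGER1, a prostaglandin E receptor (from 12.9 ± 1.3 to 44.9 ± 8.5 CPM, 1.81 ± 0.14, adjusted p = 3.1e-05), and CD22 (1.77 ± 0.40, adjusted p = 0.00983). APOE, apolipoprotein E, rose from 11.9 ± 1.2 to 39.0 ± 10.7 CPM (1.72 ± 0.17, adjusted p = 0.000202). PSAPL1 (1.60 ± 0.16), UNC13A (1.59 ± 0.17), SPOCD1 (1.47 ± 0.28), LMTK3 (1.46 ± 0.10) and B3GNT3 (1.41 ± 0.21) also rose. CD22 and KITLG depended on single libraries: CD22 lost its call without siControl 1 (log2 change 1.48) or siYAP 3 (1.24), and KITLG without siControl 2 (-0.94) or siYAP 3 (-1.02). CD22, APOE, SPOCD1, LMTK3, ARL6IP1, CENPA, KITLG and SREBF2 overlap other annotated genes.

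Among the gene lists in H1299 siYAP, the cell cycle lists moved most. All 40 mitosis genes fell, over all genes and adjusted over the list alone (median -1.04, camera adjusted p = 3.08e-45, and adjusted p = 0.349 with an estimated correlation), among them CENPF (-1.19 ± 0.17) and KIF2C (-1.25 ± 0.18, overlapped by an antisense gene). Pairs of p joined by "and" in the list paragraphs are these values in this order. Of 42 DNA replication genes, 36 fell and 0 rose (41 and 0 over the list alone, 8.87e-23 and 0.349), for example TK1, thymidine kinase (-0.97 ± 0.15). Of 24 genes of homologous recombination and the Fanconi pathway, 16 fell and 0 rose (20 and 0 over the list alone, 6.87e-10 and 0.349), including RAD51AP1 (-0.75 ± 0.15). Of 24 cholesterol synthesis genes, 16 fell and 1 rose (18 and 1 over the list alone, 1.23e-09 and 0.349). Beside SREBF2, these included the synthesis enzyme genes FDFT1 (-0.58 ± 0.10) and ACAT2 (-0.79 ± 0.14), both with antisense neighbours. Of 17 NF-kB cytokine and chemokine genes, 7 fell and 1 rose (7 and 1 over the list alone, 0.00271 and 0.349). They included BIRC3 from 175.1 to 82.5 CPM (-1.07 ± 0.20, adjusted p = 0.00408), and RELB, an NF-kB subunit (-0.58 ± 0.13), which lost its call without siYAP 3 (-0.47).

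Of 20 genes of the YAP/TAZ target signature, 7 fell and 1 rose in H1299 siYAP (7 and 3 over the list alone, median -0.14, camera adjusted p = 0.0396; adjusted p = 0.589 with an estimated correlation). The lower members were CYR61, CTGF, IGFBP3 (-1.10 ± 0.30), TGFB2 (-0.90 ± 0.23), NUAK2 (-0.76 ± 0.21), GADD45A (-0.44 ± 0.10) and AMOTL2 (-0.41 ± 0.13), and the higher one was CCDC80 (0.74 ± 0.11, adjusted p = 0.00145). With the block 8 fell and 3 rose, with AXL (-0.30), FJX1 (0.44) and RBMS3 (0.36) added. CTGF, TGFB2 and AMOTL2 overlap other annotated genes. Calls were lost without siControl 1 for IGFBP3 (-1.05), TGFB2 (-0.91), NUAK2 (-0.81) and AMOTL2 (-0.48), without siControl 2 NUAK2 (-0.68) and AMOTL2 (-0.44), without siControl 3 IGFBP3 (-0.88) and AMOTL2 (-0.34). Others were lost without siYAP 1, TGFB2 (-0.93), NUAK2 (-0.58) and AMOTL2 (-0.31), without siYAP 2 IGFBP3 (-0.87), and without siYAP 3 IGFBP3 (-1.14), TGFB2 (-0.68), NUAK2 (-0.67) and AMOTL2 (-0.47). That list lost its call without siControl 1 (camera adjusted p = 0.06), siControl 3 (0.0696), siYAP 2 (0.0668) or siYAP 3 (0.0546). Of 27 Hippo pathway and TEAD genes, 8 fell and 0 rose (9 and 0 over the list alone, 0.0016 and 0.349). Among them, NF2, the tumour suppressor merlin, fell from 74.1 ± 11.4 to 38.4 ± 6.7 CPM (-0.94 ± 0.14, adjusted p = 0.00133), and TEAD1 and FRMD6 fell by 0.49 ± 0.12 and 0.50 ± 0.12. TEAD1 lost its call without siYAP 1 (-0.46) or siYAP 3 (-0.39), and FRMD6 without siControl 1 (-0.43) or siYAP 3 (-0.43). Glycolysis and hypoxia genes had 6 lower and 0 higher of 26 (6 and 1 over the list alone, 0.0412 and 0.542), including LDHA, lactate dehydrogenase A (-0.64 ± 0.16; its call was lost without siControl 1, -0.62, siYAP 1, -0.57, or siYAP 3, -0.58). The glycolysis call was lost without siControl 1 (0.0924), siControl 2 (0.0844), siYAP 2 (0.0653), siYAP 3 (0.0515) or all libraries numbered 2 (0.082). Endothelial and fibroblast markers had 4 higher and 0 lower of 10 (5 and 0 over the list alone, 0.00178 and 0.349), led by COL1A1, a fibrillar collagen gene, at 6.39 against 2.92 CPM (1.14 ± 0.18, adjusted p = 0.00175). Mitochondrially encoded transcripts had 1 higher of 13, MT-ND3 (0.46 ± 0.12), and 0 lower (1 and 0 over the list alone, 0.00779 and 0.607), a call lost without siControl 2 (0.194) or all libraries numbered 2 (0.101). MT-ND3 lost its own call without siControl 1 (0.47), siControl 2 (0.40), siYAP 1 (0.42) or siYAP 3 (0.48).

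The other lists did not pass without the block in H1299 siYAP. With it, immediate early genes (camera adjusted p = 0.0529, with the block 0.00488), TGF-beta response (0.144, 0.0305), p53 targets (0.0582, 0.0333) and actin cytoskeleton genes (0.0738, 0.0341) passed as lower, with adjusted p from 0.201 to 0.429 for the lists called with the block with an estimated correlation. These lists also passed without siControl 3 (0.000979, 0.00497, 0.0282 and 0.0203), as did amino acid stress genes (0.154 with all libraries, 0.0242), and the immediate early list passed without siYAP 2 (0.00565) or siTAZ 3 (0.039). Within them, ATF3 and the growth inhibitor genes CDKN2B (-1.02 ± 0.15, adjusted p = 0.00145) and CDKN1A (-0.69 ± 0.13, adjusted p = 0.00406, overlapped by an antisense transcript) fell. In the lists of extracellular matrix proteins (camera adjusted p = 0.354), remodelling enzymes (0.767), integrins (0.639), epithelial markers (0.355), mesenchymal markers (0.966, with a median of -0.05 and a mean of 0.07), NRF2 targets (0.3), interferon response (0.099) and lung lineage (0.0926), members went both ways or few passed. MMP14, a membrane metalloproteinase, rose from 230.4 ± 34.9 to 421.2 ± 30.5 CPM (0.88 ± 0.11, adjusted p = 0.000692), while CAV1, caveolin 1, fell from 283.2 to 181.1 CPM (-0.63 ± 0.10, adjusted p = 0.00191). With the block, 4461 genes were called in H1299 siYAP, in place of 2625. Without siControl 1 there were 1127, without siControl 3 1568, without siYAP 1 1124 and without siYAP 3 1139.

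The same question was asked of TAZ by comparing siTAZ with siControl in H1299. CYR61 fell from 430.0 ± 148 to 135.9 ± 37.6 CPM (-1.65 ± 0.23, adjusted p = 0.000693) and CTGF from 105.9 ± 18.5 to 41.9 ± 6.1 CPM (-1.33 ± 0.13, adjusted p = 0.000316). MYC, a driver of cell growth, fell from 137.9 ± 4.1 to 70.4 ± 1.8 CPM (-0.96 ± 0.11, adjusted p = 0.000334). In the other direction, MMP14 rose from 230.4 ± 34.9 to 519.5 ± 7.3 CPM (1.19 ± 0.11, adjusted p = 0.00022) and FN1, fibronectin, from 66.6 ± 16.4 to 121.1 ± 22.5 CPM (0.88 ± 0.19, adjusted p = 0.00634). Of 15775 genes, 1717 were higher and 1963 lower (23.3%), and 455 changed at least 2-fold.

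Under the same conditions, the largest decreases in H1299 siTAZ apart from WWTR1 were in DKK1, a secreted WNT antagonist (from 19.2 ± 9.2 to 4.60 CPM, -2.05 ± 0.34, adjusted p = 0.00153), CYR61, ADAMTS6, a secreted metalloproteinase (from 19.2 ± 4.1 to 6.12 ± 0.20 CPM, 3.12-fold, adjusted p = 0.00022), and RFLNA (-1.56 ± 0.19, adjusted p = 0.000388). SLC7A2, an amino acid transporter (-1.41 ± 0.19), OIP5 (-1.36 ± 0.21), XRCC2 (-1.35 ± 0.18), CTGF, and ANLN, anillin (from 512.8 ± 142 to 206.3 ± 40.6 CPM, -1.30 ± 0.20, adjusted p = 0.00106), followed. The largest increases among such genes were in ABCC3, an exporter (from 6.31 ± 2.15 to 27.2 ± 9.5 CPM, 2.12 ± 0.26, adjusted p = 0.000401), and SOX4, a transcription factor (from 28.2 ± 19.9 to 95.5 ± 15.6 CPM, 1.78 ± 0.36, adjusted p = 0.00407). SNED1 (1.73 ± 0.20) and SPOCD1 (1.72 ± 0.28) rose as well. MMP11, a matrix metalloproteinase (1.5 ± 0.17), BMF, pro-apoptotic (from 25.7 ± 8.3 to 72.0 ± 12.4 CPM, 1.5 ± 0.23, adjusted p = 0.001), DEPTOR, an inhibitor of mTOR (1.5 ± 0.28), TMEM229B (1.44 ± 0.18) and SAMD11 (1.44 ± 0.24) also rose. ABCA1, the cholesterol exporter, rose from 22.7 ± 3.1 to 59.9 ± 11.8 CPM (1.41 ± 0.15, adjusted p = 0.000325). SOX4, SNED1, SPOCD1, MMP11, BMF, DEPTOR, SAMD11, DKK1, RFLNA, OIP5, CTGF and ANLN overlap other annotated genes.

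In H1299 siTAZ, all 42 replication genes fell over all genes and adjusted over the list alone (median -0.75, camera adjusted p = 4.94e-40, and adjusted p = 0.349 with an estimated correlation), with CDC6 (from 64.1 to 28.7 CPM, -1.15 ± 0.13) and ORC1 (from 44.5 to 19.7 CPM, -1.16 ± 0.13). MCM6 fell from 186.8 to 105.2 CPM (-0.82 ± 0.09). Of the 40 mitosis genes, 39 fell (40 over the list alone, 2.09e-23 and 0.349), among them CDK1 from 64.7 to 31.7 CPM. Of 24 recombination and Fanconi genes, 21 fell (23 over the list alone, 1.1e-13 and 0.349), including EXO1 (-0.90 ± 0.14). Of 24 cholesterol synthesis genes, 13 fell and 0 rose (17 and 1 over the list alone, 1.82e-08 and 0.349), including MVD from 591.9 to 287.1 CPM (-1.03 ± 0.17). Of 26 glycolysis and hypoxia genes, 10 fell and 2 rose (13 and 2 over the list alone, 0.00115 and 0.349), with HK2, a hexokinase, at 23.6 against 43.4 CPM (-0.87 ± 0.11, antisense neighbour) and ADM, adrenomedullin, at 16.0 against 7.61 CPM (1.09 ± 0.16). Of 25 unfolded protein and amino acid stress genes, 8 fell and 0 rose (10 and 1 over the list alone, 0.00178 and 0.349), including the serine synthesis genes PHGDH (-0.74 ± 0.12) and PSAT1 (-0.92 ± 0.15).

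Lists of the cell surface and matrix passed as higher in H1299 siTAZ. Of 31 extracellular matrix protein genes, 10 rose and 0 fell (10 and 0 over the list alone, camera adjusted p = 0.000106, and adjusted p = 0.349 with an estimated correlation). Of 30 remodelling enzymes and inhibitors, 14 rose and 2 fell (14 and 3 over the list alone, 8.24e-05 and 0.349). Beside FN1 and MMP14, ADAM19, a membrane metalloproteinase, rose from 47.1 ± 2.7 to 112.5 ± 13.6 CPM (1.27 ± 0.11, adjusted p = 0.00022, antisense neighbour) and COL1A1 by 0.83 ± 0.18. Of 22 TGF-beta response genes, 11 rose and 1 fell (11 and 1 over the list alone, 3.73e-05 and 0.349), including LTBP3 from 172.9 to 318.2 CPM (0.89 ± 0.10). Endothelial and fibroblast markers had 5 higher and 0 lower of 10 (6 and 0 over the list alone, 0.0183 and 0.349). Integrins and focal adhesion genes had 9 higher and 2 lower of 29 (14 and 2 over the list alone, 0.0189 and 0.607). ITGB8 rose (1.16 ± 0.23, antisense neighbour), while CAV1 (-0.72 ± 0.10) and FERMT2, kindlin 2 (-0.69 ± 0.10, antisense neighbour) fell. The integrin call was lost without siTAZ 1 (0.0582), the endothelial one without all libraries numbered 2 (0.082).

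The YAP/TAZ target signature had 6 lower and 2 higher of 20 members in H1299 siTAZ (6 and 2 over the list alone, median -0.19). It did not pass without the block (camera adjusted p = 0.0679), and did with it (0.0257; adjusted p = 0.419 with an estimated correlation). It also passed without siControl 2 (0.00695), siTAZ 1 (0.00657) or siTAZ 3 (0.0423). Beside CYR61 and CTGF, TGFB2 (-0.80 ± 0.23), AMOTL2 (-0.44), GADD45A (-0.34) and ASAP1 (-0.31) fell, and CCDC80 (0.88 ± 0.11) and RBMS3 (0.56 ± 0.14) rose. With the block 9 fell and 3 rose, with PTPN14 (-0.25), CRIM1 (-0.35), IGFBP3 (-0.46) and NT5E (0.22) added. TGFB2, AMOTL2 and RBMS3 overlap other genes. Calls were lost without siControl 1 for TGFB2 (-0.79) and ASAP1 (-0.22), without siControl 2 for TGFB2 (-0.72) and GADD45A (-0.32), and without siControl 3 for AMOTL2 (-0.36) and GADD45A (-0.31). They were also lost without siTAZ 1 for AMOTL2 (-0.45) and GADD45A (-0.30), without siTAZ 2 for AMOTL2 (-0.32) and ASAP1 (-0.28), and without siTAZ 3 for TGFB2 (-0.58), GADD45A (-0.37) and ASAP1 (-0.27). Of 27 Hippo pathway genes, 5 fell and 2 rose (5 and 2 over the list alone, camera adjusted p = 0.144), with NF2 at 32.9 ± 3.6 against 74.1 ± 11.4 CPM (-1.16 ± 0.14, adjusted p = 0.000334) and TEAD4 lower (-0.53 ± 0.10). NRF2 targets (0.0582, with the block 0.0214) and lung lineage genes (0.0596, with the block 0.0232) passed as lower and higher with the block, with adjusted p up to 0.419 with an estimated correlation for lists called with the block. NRF2 targets also passed without siControl 1 (0.0438), siControl 3 (0.0095) or siTAZ 2 (0.0352), and lung lineage genes without siControl 1 (0.0348), siControl 3 (0.0449), siTAZ 3 (0.047) or all libraries numbered 2 (0.0495). SOX2, of the lung lineage list, rose from 20.5 ± 9.2 to 46.4 ± 11.8 CPM (1.20 ± 0.28, adjusted p = 0.0093), and SLC7A11, an NRF2 target, fell (-1.14 ± 0.20, adjusted p = 0.00202). NF-kB genes (camera adjusted p = 0.134) passed as higher without siTAZ 3 (0.0344), and mitochondrially encoded transcripts (0.424) without siControl 3 (0.029) or siTAZ 2 (0.0329). Actin (0.314), interferon (0.173), mesenchymal (0.355), immediate early (0.415), epithelial (0.965) and p53 (0.994) genes did not pass, and for the last pair the medians of 0.05 and 0.06 lay opposite to the direction of the test. With the block, 5606 genes were called in H1299 siTAZ in place of 3680, and there were 1820 without siControl 1 and 1715 without siTAZ 3.

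**Figure D3:**
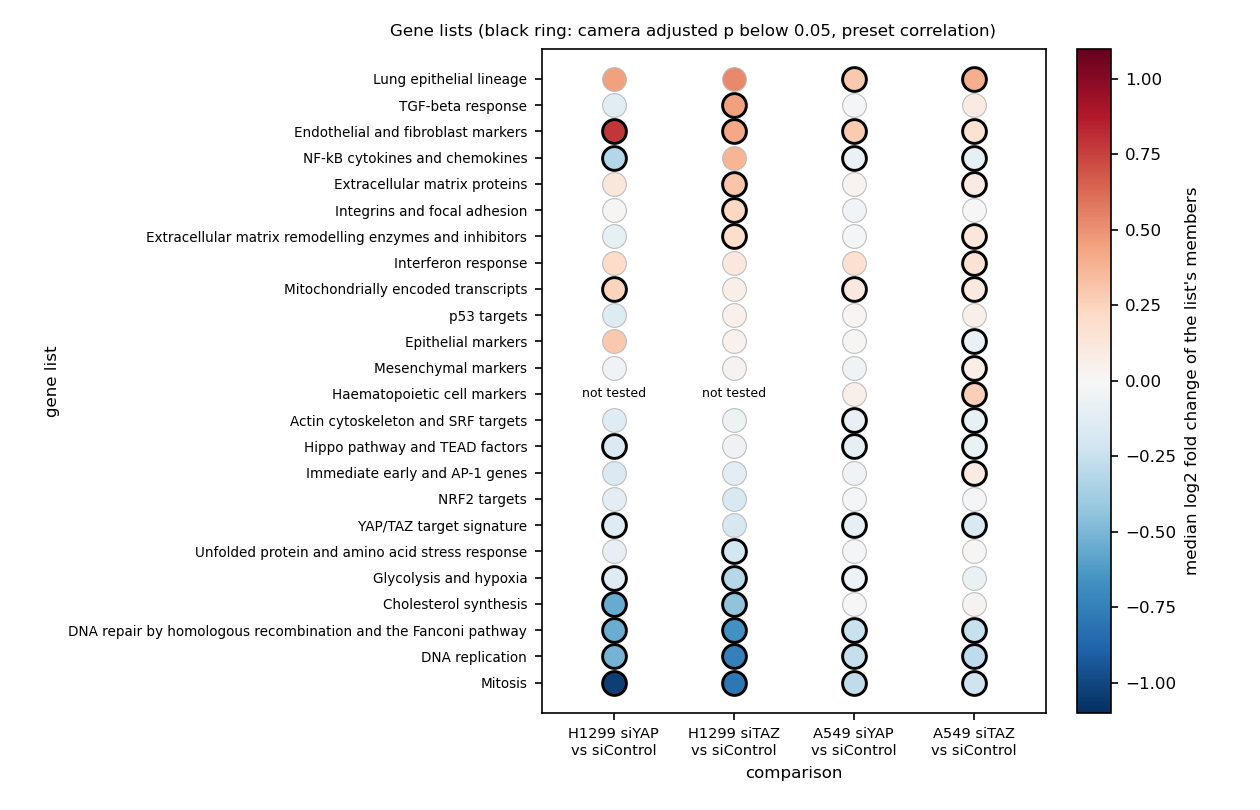
Median log2 fold change of each gene list (colour) in the 4 knockdown against control comparisons, from the fits without the block, with a black ring where camera with the preset correlation gave an adjusted p below 0.05. The 3 cell cycle lists at the bottom are ringed in all 4 columns, and none of the 49 ringed calls holds with an estimated correlation.

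To compare the knockdowns, shared calls were counted. In H1299, 578 genes were higher under both siRNAs and 702 lower under both, where independent lists of these sizes would share 135 and 172, and 16 rose under siYAP and fell under siTAZ and 35 the reverse. Across the 15775 genes, which are not independent replicates, the log2 changes of siYAP and siTAZ correlated with r = 0.61 (Spearman's rho 0.615, jackknife SE of r over libraries 0.0988). Both comparisons share the same controls: 20 simulations of unchanged groups and controls gave r = 0.514 on average (highest 0.531). The covariance was 0.109 against 0.0227 simulated, a difference of 0.0858. With the block 1126 genes were higher under both and 1304 lower (357 and 438 for independent lists), and 63 and 114 opposite. The 3 controls cannot be split, so part of the excess overlap may come from sharing them. In A549, without the block, the correlation was 0.56 (jackknife SE 0.329, simulated 0.506, highest 0.523) and the covariance 0.0265 (0.0106 with at least 5 CPM, not simulated) against 0.0328 simulated, a difference of -0.00625. With the block the correlation and covariance in A549 were 0.545 (simulated 0.498, highest 0.513) and 0.0251 against 0.0114, a difference of 0.0137, with 204 genes higher under both (28.9 for independent lists) and 260 lower (31.1).

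**Figure D4:**
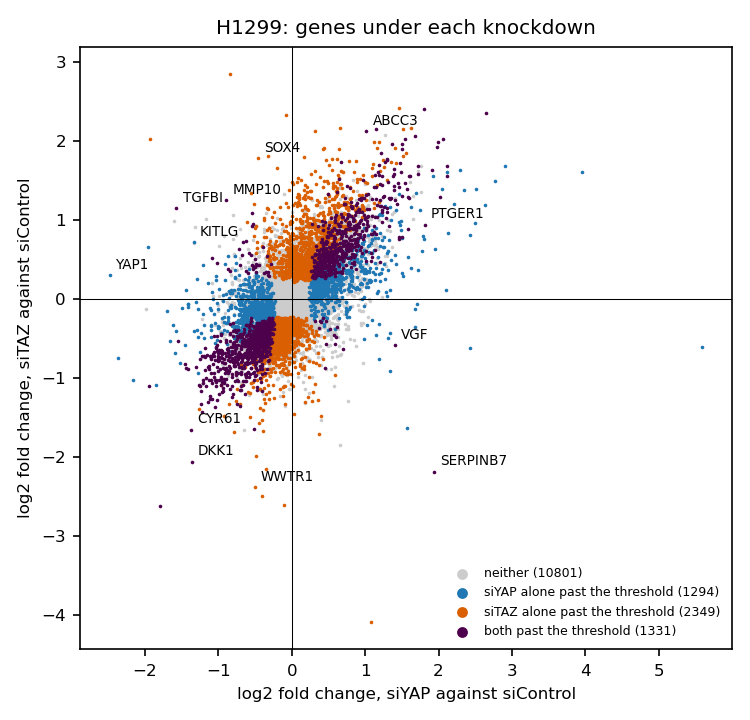
Log2 fold change of each gene in H1299 under siYAP (horizontal) and siTAZ (vertical) against siControl, coloured by which comparison passed an adjusted p below 0.05, with some of the named genes labelled. The threshold was passed by 1331 genes under both siRNAs, by 1294 under siYAP alone and by 2349 under siTAZ alone.

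Where YAP and TAZ differ was tested directly in H1299 by comparing siYAP with siTAZ. SERPINB7 was 11.7 ± 5.4 CPM under siYAP and 0.669 CPM under siTAZ, a 17.3-fold difference (log2 4.11 ± 0.39, adjusted p = 0.0001), and lay above the controls under siYAP (1.93) and below them under siTAZ (-2.18). VGF was 634.9 ± 79.5 against 160.9 ± 21.1 CPM (1.98 ± 0.13, adjusted p = 3.44e-06), again on opposite sides of the controls (1.4 and -0.58). In the reverse direction, TGFBI was 3.14 ± 2.67 under siYAP against 20.4 ± 3.8 CPM under siTAZ (-2.73 ± 0.43, adjusted p = 0.00161), SOX4 20.3 ± 8.2 against 95.5 ± 15.6 CPM (-2.24 ± 0.36, adjusted p = 0.00176). MMP10, a stromelysin, was 4.8 against 21.2 CPM (-2.14 ± 0.22, adjusted p = 0.000137), and KITLG 5.70 against 23.5 CPM (-2.05 ± 0.33, adjusted p = 0.00158). LRRN4CL (1.81 ± 0.23) and SNCG, gamma-synuclein (1.77 ± 0.24), were higher under siYAP. WWTR1 and YAP1 themselves differed by 1.88 ± 0.28 and -2.78 ± 0.15. In all, 883 genes were higher under siYAP and 963 lower (11.7% of those tested), 263 of them at least 2-fold.

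TGF-beta response genes were lower under siYAP than under siTAZ in H1299: 10 of 22 were lower and 1 higher (13 and 1 over the list alone, camera adjusted p = 1.41e-10; adjusted p = 0.47 with an estimated correlation). Among them, CDKN2B was 28.3 against 78.3 CPM (-1.47 ± 0.15, adjusted p = 0.000134). The co-repressor gene TGIF1 differed by -0.73 ± 0.08, and PMEPA1, with an antisense neighbour, was 22.2 against 66.5 CPM (-1.58 ± 0.23). NF-kB genes had 8 lower and 0 higher of 17 (10 and 0 over the list alone, 6.12e-07 and 0.47), with RELB at 85.8 against 165.9 CPM and TNFAIP3 at -1.24 ± 0.16. Remodelling enzymes had 11 lower and 2 higher of 30 (13 and 2 over the list alone, 6.12e-07 and 0.507), with PLOD2 at 30.9 against 90.4 CPM (-1.55 ± 0.16) and ADAM19 at -1.09 ± 0.11. Extracellular matrix proteins had 7 lower and 0 higher of 31 (9 and 0 over the list alone, 0.000974 and 0.877), including FN1 at 52.1 against 121.1 CPM (-1.22 ± 0.19, adjusted p = 0.0016). For replication genes the test pointed to higher levels under siYAP, and 5 of 42 members were higher and 0 lower (5 and 0 over the list alone, 5.77e-06 and 0.903), for example ORC1 at 33.3 against 19.7 CPM. For mitosis genes the test pointed lower, and 1 of 40 members passed, CENPF (-0.56 ± 0.17), and 0 over the list alone (0.00352 and 0.914). With the block 6 were lower, CCNB2 and CENPA among them, and 3 over the list alone. The mitosis call was lost without siYAP 1 (0.145), siYAP 3 (0.123) or siTAZ 2 (0.152), and that of CENPF without siYAP 1 (-0.54), siYAP 3 (-0.43), siTAZ 1 (-0.47) or siTAZ 3 (-0.65). Recombination genes (camera adjusted p = 0.105) passed as higher without siYAP 1 (0.0288), siYAP 3 (0.0104) or siTAZ 1 (0.0126).

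With the block, integrins (camera adjusted p = 0.0541, with the block 0.0285), p53 targets (0.0791, 0.0223), amino acid stress genes (0.0701, 0.0285) and mitochondrially encoded transcripts (0.105, 0.0285) also differed between siYAP and siTAZ in H1299, with adjusted p from 0.204 to 0.813 with an estimated correlation for lists called with the block. Single genes of other lists differed too: HK2 was 47.5 under siYAP against 23.6 CPM under siTAZ (1.01 ± 0.11, adjusted p = 0.000197) and ADM 5.18 against 16.0 CPM (-1.63 ± 0.16, adjusted p = 0.000108). SREBF2 differed by -1.02 ± 0.13 and SOX2 by -1.72 ± 0.29. Of 20 signature genes 3 were higher and 1 lower (4 and 3 with the block): CTGF (0.58 ± 0.13, not called without siTAZ 3, 0.51), ASAP1 (0.30, not called without any 1 siYAP or siTAZ library, 0.26 to 0.34), CRIM1 (0.50, antisense neighbour, likewise except siTAZ 1, 0.37 to 0.55) and NUAK2 (-0.79, not called without siYAP 1, -0.61, siYAP 3, -0.73, or siTAZ 1, -0.74). The block added FJX1 (0.38), NT5E (-0.32) and IGFBP3 (-0.65). Without the block, integrins also passed without siControl 1 (0.0472), siControl 3 (0.0498), siYAP 1 (0.000718) or siTAZ 2 (0.00335), and p53 targets without siTAZ 3 (0.0451) or all libraries numbered 2 (0.0465). So did amino acid stress genes without siControl 2 (0.0447), siControl 3 (0.0386), siYAP 3 (0.0158) or siTAZ 1 (0.0162), and mitochondrially encoded transcripts without siTAZ 1 (0.0105) or siTAZ 3 (0.0184). The remaining lists, from Hippo pathway genes (0.154) to the signature (0.927), did not pass. The count of called genes was 3399 with the block in place of 1846. It was 1190 without siYAP 1, 856 without siYAP 3, 1119 without siTAZ 1 and 925 without siTAZ 3.

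In A549, the same question about YAP gave much smaller changes. The fit without the block called 1 gene lower, YAP1 itself, and 0 higher of 16008 (410 at an unadjusted p below 0.05; DESeq2 called 6 and limma-voom 1). With the replicate block, edgeR called 401 higher and 508 lower, 15 of them at least 2-fold. The values that follow are from the fit with the block, and outside it the adjusted p of these genes did not pass. PLOD2 fell from 216.1 to 138.3 CPM (-0.63 ± 0.04, adjusted p = 1.36e-13), EIF4EBP2, a repressor of translation, from 62.8 to 41.3 CPM (-0.60 ± 0.05, adjusted p = 2.34e-09), and COMMD8 from 13.9 to 8.95 CPM (-0.60 ± 0.09). AMOTL2, an angiomotin and a YAP target, fell from 51.2 to 36.1 CPM (-0.52 ± 0.06, adjusted p = 5.1e-07, overlapped by a pseudogene) and CYR61 from 22.4 to 15.4 CPM (-0.51 ± 0.08, adjusted p = 2.97e-05). NTS, the neurotensin precursor, rose from 26.9 to 39.5 CPM (0.55 ± 0.06, adjusted p = 2.63e-08), and MUC5AC, a gel-forming mucin, from 25.4 to 36.0 CPM (0.55 ± 0.06, adjusted p = 2.92e-07). SERPINA6, corticosteroid-binding globulin, rose from 10.5 to 16.1 CPM (0.61 ± 0.08) and NEB, nebulin, from 6.51 to 12.1 CPM (0.93 ± 0.10, antisense neighbour). HLA-DMB (0.53 ± 0.09), which overlaps another gene, and SKA3 (-0.56) also passed. HABP2, SSPO, KCNJ16, FGB, CEACAM7, XDH, MCM10 and MARCH4 passed too, but lost their calls without replicate 2, where their log2 changes were 0.56, 0.40, 0.31, 0.37, 0.44, -0.63, -0.38 and -0.45. Without replicate 1, 2 or 3 of each group the blocked count was 320, 157 and 739.

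Gene lists in A549 siYAP were again led by cell division. All 15 calls of the fit with the block were lost at adjusted p = 0.2 to adjusted p = 0.46 with an estimated correlation. With the block, 32 of 40 mitosis genes fell (36 over the list alone, 7.22e-42 and 0.2), 24 of 42 replication genes (32 over the list alone, 3.46e-25 and 0.201) and 6 of 24 recombination and Fanconi genes (12 over the list alone, 7.2e-08 and 0.2), with medians of -0.27, -0.26 and -0.23. Examples are RRM2, a ribonucleotide reductase subunit, from 41.6 to 30.7 CPM (-0.43 ± 0.05), CCNB1, cyclin B1 (-0.31 ± 0.05), and FANCI (-0.37 ± 0.05). Of 22 genes of the YAP/TAZ target signature, 8 fell and 0 rose (13 and 1 over the list alone, 4.99e-08 and 0.201), namely CYR61, AMOTL2, CTGF (-0.45 ± 0.10), TGFB2 (-0.31), ANKRD1 (-0.31 ± 0.09), MYOF (-0.26 ± 0.04), LATS2 (-0.24) and ARHGEF17 (-0.20). With the same block, CTGF did not pass in DESeq2 (adjusted p = 0.369) or with robust shrinkage (0.246), and ANKRD1, LATS2 and ARHGEF17 did not in DESeq2 (0.179, 0.189 and 0.107) or limma-voom (0.189, 0.0789 and 0.0706). Of 27 Hippo pathway genes, 8 fell and 0 rose (11 and 1 over the list alone, 2.81e-07 and 0.2), with AJUBA at -0.49 ± 0.05. Actin genes (4 lower, 1 higher, 0.000598 and 0.201), glycolysis genes (4 lower, 9.69e-05 and 0.201), with LDHA at -0.25 ± 0.04, and NF-kB genes (3 lower, 0.00438 and 0.291) passed as lower. Remodelling enzymes (5 lower, 0.00378 and 0.28), TGF-beta response (4 lower, 1 higher, 0.0243 and 0.248) and immediate early genes (3 lower, 0.0244 and 0.314) did so too. Lung lineage genes (2 higher of 11, 1.24e-05 and 0.2), mitochondrially encoded transcripts (2 higher of 13, 2.73e-08 and 0.308), endothelial and fibroblast markers (2 higher, 0.00733 and 0.201) and interferon genes (2 higher, 0.00723 and 0.46) passed as higher, with MUC5B, another mucin, at 140.3 against 114.8 CPM (0.31 ± 0.05). With the block, calls were also lost without replicate 1 (immediate early 0.128, ANKRD1 -0.29, ARHGEF17 -0.16, LATS2 -0.28), replicate 2 (remodelling 0.0992, TGF-beta 0.185, NF-kB 0.12, immediate early 0.138, ANKRD1 -0.31, ARHGEF17 -0.20, CTGF -0.42, LATS2 -0.21, MUC5B 0.20, TGFB2 -0.25), with log2 changes for the genes. Without replicate 3 the calls lost were interferon (0.66), endothelial and fibroblast (0.113), ANKRD1 (-0.36) and LATS2 (-0.22). Outside the block the remodelling (0.209), TGF-beta (0.371), interferon (0.0679) and immediate early lists (0.0635) did not pass and the other 11 did, at adjusted p = 0.181 to adjusted p = 0.607 with an estimated correlation. Of these 11, Hippo pathway and glycolysis genes alone kept their calls with any library left out. Others were lost without siControl 1 (recombination 0.12, endothelial 0.302), siControl 2 (replication 0.272, mitosis 0.756, recombination 0.513) or siControl 3 (signature 0.141, actin 0.341, NF-kB 0.758, lung 0.0789), and without siYAP 1 (actin 0.129, NF-kB 0.159), siYAP 2 (signature 0.151, actin 0.16, NF-kB 0.677) or siYAP 3 (replication 0.969, mitosis 0.591, recombination 0.56, endothelial 0.403, mitochondrially encoded 0.281). With the same sign, lists also passed there without siControl 2 (remodelling 0.00588, haematopoietic 0.0494), siControl 3 (interferon 0.00241, p53 0.0223, NRF2 0.0334), siYAP 1 (interferon 0.000382, p53 0.0198, NRF2 0.0167, cholesterol 3.75e-05, amino acid stress 0.0323, haematopoietic 0.0323) or siYAP 2 (interferon 0.00621). Others passed without siYAP 3 (remodelling 0.000111, TGF-beta 0.0421, immediate early 0.00389, matrix proteins 0.0217, integrin 0.04), siTAZ 1 (interferon 0.0488) or siTAZ 3 (interferon 0.045). With the block, the matrix protein (0.875), integrin (0.172), epithelial (0.607), mesenchymal (0.205), p53 (0.448), NRF2 (0.092), cholesterol (0.981), amino acid stress (0.162) and haematopoietic (0.12) lists did not pass. In the matrix protein, integrin, epithelial, mesenchymal and cholesterol lists the median, the mean and the test differed in sign.

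For TAZ in A549, the fit without the block likewise called only the target, WWTR1, of 16008 genes (701 at an unadjusted p below 0.05; DESeq2 called 52 and limma-voom 2). It called 2 without siControl 3 or siTAZ 1. With the block, 1154 were higher and 980 lower, 54 of them at least 2-fold. From that fit, ANKRD1, a classical YAP and TAZ target, fell from 14.1 to 4.64 CPM (-1.62 ± 0.11, adjusted p = 2.36e-13), CYR61 from 22.4 to 11 CPM (-1.03 ± 0.08, adjusted p = 5.57e-12) and CTGF from 19.6 to 9.22 CPM (-1.08 ± 0.11, adjusted p = 3.23e-09). TFPI2, a protease inhibitor, fell from 441.5 ± 58.8 to 212.7 ± 47.3 CPM (-1.07 ± 0.05, adjusted p = 3.44e-18), WISP2 from 36.0 to 19.5 CPM (-0.93 ± 0.07) and AMOTL2 from 51.2 to 28.0 CPM (-0.90 ± 0.06, adjusted p = 8.57e-13). ANXA8L1 (-0.92), PDZK1IP1 (-0.90) and C1orf116 (-0.82 ± 0.08) also fell. NEB rose from 6.51 to 15.2 CPM (1.28 ± 0.10) and TCN1, a vitamin B12 binding protein gene, from 5.88 to 11.4 CPM (0.98 ± 0.10, adjusted p = 2.55e-09). MMP2, gelatinase A, rose from 6.74 to 12.2 CPM (0.86 ± 0.09, adjusted p = 2.1e-08) and CST1, a cystatin, from 12.2 to 21.1 CPM (0.77 ± 0.07). SLC4A8 (1.12 ± 0.12), HABP2 (0.99), MAF (0.85 ± 0.11), SYT11 (0.82 ± 0.08), CACNG7 (0.80) and SERPINA6 (0.78 ± 0.08) rose too. NEB, SLC4A8, HABP2, MMP2, CTGF, TFPI2, ANXA8L1 and AMOTL2 overlap other annotated genes. Without replicate 1, 2 or 3 of each group the blocked count was 1234, 940 and 1593.

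With the block, the signature in A549 siTAZ had 11 lower and 2 higher of 22 (12 and 2 over the list alone, median -0.22, camera adjusted p = 4.63e-17, and adjusted p = 0.2 with an estimated correlation). All 17 list calls of this fit were lost at adjusted p = 0.2 to adjusted p = 0.474 with an estimated correlation. MYOF, myoferlin, fell from 836.6 to 618.1 CPM (-0.44 ± 0.04). So did TGFB2 (-0.61), NUAK2 (-0.49), CRIM1 (-0.43), DOCK5 (-0.31), AXL (-0.24) and ARHGEF17 (-0.18, not called in DESeq2, adjusted p = 0.114, or without replicate 1, -0.18, or 2, -0.15). IGFBP3 rose from 156.5 to 205.2 CPM (0.39 ± 0.05) and NT5E by 0.36 ± 0.05. Hippo pathway genes had 6 lower and 3 higher of 27 (9.25e-05 and 0.201), with AJUBA at -0.68 ± 0.05. Of 42 replication genes 32 fell (35 over the list alone, 8.89e-20 and 0.201), of 40 mitosis genes 26 (33 over the list alone, 5.95e-21 and 0.2) and of 24 recombination and Fanconi genes 7 (9 over the list alone, 1.12e-06 and 0.2), and none of their members rose. Matrix protein genes had 9 higher and 2 lower of 36 (11 and 3 over the list alone, 0.000751 and 0.2), with FN1 at 1293 ± 199 against 881.2 ± 184 CPM (0.57 ± 0.04, adjusted p = 1.27e-12) and VCAN, versican, at 0.29 ± 0.04. Actin genes had 11 lower and 1 higher (2.83e-06 and 0.2), with MYLK, myosin light chain kinase, at -0.51 ± 0.06. Epithelial markers had 5 lower and 0 higher (0.00396 and 0.308), with the keratin genes KRT18 (from 1538 to 1064 CPM) and KRT7 (from 775.0 to 522.4 CPM), both with antisense neighbours. NF-kB genes had 6 lower and 0 higher (9.57e-06 and 0.201), with CXCL5, a neutrophil chemokine, from 193.5 ± 18.5 to 114.7 ± 32.1 CPM (-0.78 ± 0.05, adjusted p = 2.19e-13). Glycolysis genes had 8 lower and 1 higher (0.00384 and 0.28). Lung lineage genes had 4 higher of 11 (7 over the list alone, 1.24e-05 and 0.2), with MUC5AC from 25.4 to 38.1 CPM (0.60 ± 0.06). Immediate early genes had 9 higher and 3 lower (0.0263 and 0.314), with FOS from 7.49 to 11.6 CPM. Interferon genes had 8 higher and 1 lower (0.00743 and 0.474) and p53 targets 5 higher (0.00409 and 0.385). Cholesterol synthesis had 5 higher (0.0444 and 0.385), endothelial and fibroblast markers 3 higher (0.0246 and 0.223) and mitochondrially encoded transcripts 1 higher of 13 (0.000545 and 0.414).

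With the block, list calls in A549 siTAZ were lost without replicate 1 (cholesterol, 0.128), replicate 2 (p53, 0.168) or replicate 3 (interferon 0.91, immediate early 0.113, cholesterol 0.113, endothelial and fibroblast 0.0527, mitochondrially encoded 0.0675). Remodelling enzymes (camera adjusted p = 0.116, without the block 0.0344), mesenchymal markers (0.526, 0.0359) and haematopoietic markers (0.0607, 0.00695) passed as higher only outside the block. There p53 targets (0.0679), cholesterol synthesis (0.416) and glycolysis (0.0582) did not pass and 17 lists were called, at adjusted p = 0.25 to adjusted p = 0.696 with an estimated correlation. Of these 17, the signature, Hippo pathway and lung lineage genes kept their calls with any library left out. Others were lost without siControl 1 (mitosis 0.162, recombination 0.083, matrix proteins 0.0713, remodelling 0.145, epithelial 0.127, mesenchymal 0.26, interferon 0.1, immediate early 0.102, haematopoietic 0.344, endothelial 0.0713). Calls fell away without siControl 2 (replication 0.164, mitosis 0.786, recombination 0.326, matrix proteins 0.574, remodelling 0.584, epithelial 0.12, mesenchymal 0.111, interferon 0.164, immediate early 0.0942, mitochondrially encoded 0.134). So they did without siControl 3 (actin 0.0799, NF-kB 0.181, immediate early 0.0585). Others were lost without siYAP 1 (immediate early 0.0502, haematopoietic 0.0501), siYAP 2 (immediate early 0.0545), siTAZ 1 (mitochondrially encoded 0.0648) or siTAZ 2 (NF-kB 0.113, immediate early 0.0515, haematopoietic 0.107). Most were lost without siTAZ 3 (replication 0.72, mitosis 0.153, recombination 0.966, matrix proteins 0.877, remodelling 0.879, epithelial 0.719, mesenchymal 0.478, interferon 0.331, immediate early 0.234, endothelial 0.0948, mitochondrially encoded 0.374). With the same sign, lists also passed there without siControl 1 (cholesterol 0.000125), siControl 3 (p53 0.000487), siTAZ 1 (p53 0.00118, NRF2 0.0337), siTAZ 2 (glycolysis 0.0236) or siTAZ 3 (cholesterol 0.045). With the block and without replicate 2, the remodelling enzymes (0.0436) and the NRF2 targets (0.0739 with all libraries, 0.0308) passed. Integrins (0.439), TGF-beta response (0.563) and amino acid stress genes (0.642) did not pass in either fit.

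Compared directly in A549, siYAP and siTAZ differed without the block in the 2 targets alone, WWTR1 (1.45 ± 0.12, adjusted p = 0.00279) and YAP1 (-1.80 ± 0.09, adjusted p = 7.14e-05), of 16008 genes (558 at an unadjusted p below 0.05; DESeq2 called 19 and limma-voom 2). With the block, 403 genes were higher under siYAP and 724 lower, 23 of them at least 2-fold. ANKRD1 (1.31 ± 0.11, adjusted p = 1.91e-10), WISP2 (0.82 ± 0.07), TFPI2 (0.67 ± 0.05, adjusted p = 6.3e-12) and C1orf116 (0.66 ± 0.08) were higher under siYAP. TCN1 (-1.03 ± 0.10), SLC4A8 (-0.87 ± 0.12), EIF4EBP2 (-0.80 ± 0.05, adjusted p = 2.23e-13) and MMP2 (-0.79 ± 0.09) were lower. Signature genes were higher under siYAP with the block, 9 against 2 lower of 22 (11 and 2 over the list alone, camera adjusted p = 1.2e-05; adjusted p = 0.335 with an estimated correlation), including CYR61 (0.53 ± 0.08) and CTGF (0.63 ± 0.11). CTGF was not called without replicate 3 (0.33), in DESeq2 (adjusted p = 0.268) or with robust shrinkage (0.147). Matrix protein genes had 11 lower and 1 higher (13 and 3 over the list alone, 0.00019 and 0.204), with FN1 at -0.39 ± 0.04. Remodelling enzymes had 7 lower and 2 higher (18 and 3 over the list alone, 3.57e-06 and 0.323), with PLOD2 at -0.40 ± 0.04. Immediate early genes had 8 lower and 0 higher (10 and 1 over the list alone, 2.29e-06 and 0.289), with FOS at -0.64 ± 0.09. Epithelial (camera adjusted p = 0.00615), NF-kB (0.0241) and actin genes (0.0407) also passed as higher with the block, and TGF-beta response (0.0075), p53 targets (0.0154) and cholesterol synthesis (0.0285) as lower. These were lost with an estimated correlation (0.445, 0.445, 0.451, 0.365, 0.594 and 0.517). With all libraries none of these passed outside the block, nor did the signature (0.154). The p53 call was lost without replicate 1 (0.0621) or 2 (0.101), actin without 2 (0.128), cholesterol without 2 (0.101) or 3 (0.0691) and epithelial without 3 (0.101), while mesenchymal genes (0.0712) passed without 2 (0.0141) and mitosis genes without 3 (0.00386). Outside the block matrix proteins (0.00898), remodelling enzymes (0.000496), mesenchymal markers (0.0275) and immediate early genes (8.86e-05) passed as lower, all lost with an estimated correlation (adjusted p = 0.366 to adjusted p = 0.903). Of these, the immediate early call alone held with any library left out. The others were lost without siYAP 1 (mesenchymal 0.0925), siYAP 2 (matrix proteins 0.483, remodelling 0.266, mesenchymal 0.108) or siTAZ 3 (matrix proteins 0.776, remodelling 0.37, mesenchymal 0.402). With the same sign, lists also passed there without siYAP 1 (cholesterol 1.28e-06), siYAP 2 (signature 0.00415, NF-kB 0.0152, mitosis 1.49e-05, mitochondrially encoded 0.00661) or siYAP 3 (p53 9.9e-05, epithelial 0.0444, TGF-beta 0.0108, replication 9.78e-06, recombination 0.000148, interferon 0.000183). Others passed without siTAZ 1 (p53 0.000815, epithelial 0.02), siTAZ 2 (cholesterol 0.0144, replication 0.0135, recombination 0.0386, interferon 0.0342) or siTAZ 3 (signature 0.0142, NF-kB 0.00138, actin 0.0158, cholesterol 0.0158, mitosis 1.43e-07). Without replicate 1, 2 or 3 the blocked count was 639, 289 and 703.

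Whether the same siRNA acts alike in both lines was examined over the 14027 genes tested in both. With the block, 157 genes were higher and 365 lower under siYAP in both lines, against 41.5 and 77.9 for independent lists, and 18 went in opposite directions. Under siTAZ 449 were higher and 608 lower in both, against 160 and 184, and 70 went in opposite directions. For siYAP against siTAZ there were 145 and 294, against 40.8 and 69.4, with 55 opposite. Across genes, which are not independent replicates, the log2 changes of the lines without the block correlated with r = 0.38 for siYAP (rho 0.407), 0.365 for siTAZ (rho 0.387) and 0.274 for siYAP against siTAZ (rho 0.305), from libraries that share no controls. Over libraries, the jackknife SE of r was 0.228, 0.236 and 0.113.

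Differences between the lines were tested as interactions. ARL6IP1, OSTM1, SREBF2 and PMAIP1 fell by 1.61, 1.56, 1.21 and 1.31 under siYAP in H1299 and had log2 changes of -0.22, -0.37, -0.07 and -0.23 in A549, and each difference passed (adjusted p = 0.0255 to 0.0315). Under siTAZ, ADAMTS6 and NF2 had changes of -1.64 and -1.16 in H1299 against 0.79 and -0.10 in A549, neither of which passed there (adjusted p = 1). WNT7B, a WNT ligand, ABCC3 and CD109 had 1.90, 2.12 and 1.96 against -0.06, 0.18 and 0.12 (adjusted p = 0.0164 to 0.0423). Of 15816 genes, 13 differed in the siYAP effect, 60 in the siTAZ effect and 99 in siYAP against siTAZ in edgeR without the block (1708, 2376 and 1683 at an unadjusted p below 0.05). DESeq2 called 130, 314 and 258, limma-voom 11, 49 and 76, and edgeR with the block 1712, 2797 and 1535. The closing section gives these counts with each library left out, most moved by over 1.5 times. ADAMTS6 was near the floor in A549, at 0.369 against 0.219 CPM, and WNT7B and CD109 in H1299, at 0.95 and 0.527 CPM in the controls. ARL6IP1, SREBF2 and CD109 overlap other annotated genes.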

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

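The differences between the lines were tested as interactions by edgeR in the joint fit, and each gene here passed an adjusted p below 0.05. The comparisons of slopes under incomplete knockdown and with the block were chosen only after the smaller A549 response was seen, and the splits of the libraries were planned before.

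For siYAP the joint fit called 13 genes, 8 with a higher and 5 with a lower log2 change in A549 than in H1299. The differences (A549 minus H1299) were 1.39 ± 0.23 for ARL6IP1, 1.19 ± 0.21 for OSTM1, 1.14 ± 0.17 for SREBF2, 1.08 ± 0.18 for PMAIP1 and 1.01 ± 0.15 for BTD, a biotinidase, and -2.47 ± 0.43 for COL4A6, a basement membrane collagen, -1.13 ± 0.20 for CCDC184, -1.05 ± 0.19 for CNTN1, an adhesion protein, and -0.71 ± 0.12 for FHOD1, an actin nucleator (adjusted p = 0.0255 to 0.0378). COL4A6 stood at 1.11 against 0.192 CPM in H1299 and at 65.0 against 64.0 CPM in A549. ARL6IP1, SREBF2, BTD and FHOD1 overlap other annotated genes. The count of 13 was 0 without H1299 siControl 1 or 3, H1299 siYAP 1, A549 siControl 1 or 2, or A549 siYAP 1 or 3. It was 1 without H1299 siYAP 3, 2 without A549 siYAP 2, 18 without A549 siControl 3, 37 without H1299 siControl 2 and 130 without H1299 siYAP 2.

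For siTAZ it called 60 genes, 26 higher and 34 lower in A549. The differences were 2.44 ± 0.51 for ADAMTS6, 1.18 ± 0.25 for SLC7A2, 1.07 ± 0.19 for NF2, 1.02 ± 0.18 for UAP1 and 1.01 ± 0.21 for AP1M2, and -2.10 ± 0.36 for STRA6, a retinol transporter, -1.95 ± 0.28 for WNT7B, -1.94 ± 0.29 for ABCC3, -1.83 ± 0.29 for CD109 and -1.64 ± 0.27 for ZNF469 (adjusted p = 0.0164 to 0.0466). In H1299 STRA6, WNT7B and CD109 were near the floor, at 1.18 against 0.235, 3.52 against 0.95 and 2.03 against 0.527 CPM (128 to 303 CPM in A549). STRA6 and CD109 overlap other annotated genes. The count of 60 was 4, 229 and 1 without H1299 siControl 1, 2 or 3, 9, 254 and 15 without H1299 siTAZ 1, 2 or 3, 8, 8 and 24 without A549 siControl 1, 2 or 3, and 19, 22 and 46 without A549 siTAZ 1, 2 or 3.

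For siYAP against siTAZ it called 99 genes, 61 higher and 38 lower. The differences were 2.55 ± 0.56 for TGFBI, 2.36 ± 0.35 for STRA6, 2.26 ± 0.42 for KITLG, 1.44 ± 0.20 for RNF141, a ubiquitin ligase, and 1.24 ± 0.26 for PLK2, a polo-like kinase, and -1.88 ± 0.37 for VGF, -1.70 ± 0.32 for SNCG, -1.63 ± 0.36 for COL4A6, -1.53 ± 0.25 for CEND1 and -1.28 ± 0.27 for HK2 (adjusted p = 0.011 to 0.0484). STRA6 stood at 0.222 against 1.18 CPM in H1299, COL4A6 at 1.11 against 0.379, and VGF at 1.55 against 1.60 CPM in A549. STRA6, KITLG and HK2 overlap other annotated genes. Without H1299 library 1, 2 or 3 the count of 99 was 18, 138 and 3 (siYAP) and 13, 124 and 7 (siTAZ). For A549 it was 9, 27 and 22 (siYAP) and 10, 5 and 65 (siTAZ). With the block all 29 named here passed (adjusted p up to 0.00189). Without it RNF141 alone kept its call with any library left out.

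The libraries were regrouped within each line. For siYAP, 6 of 40 splits, the real one included, called at least 13 genes (highest other 1225). For siTAZ 5 of 40 called at least 60 (highest other 3036), and for siYAP against siTAZ 5 of 40 called at least 99 (highest other 1315). All the other splits that large kept the 3 H1299 libraries of each group together, and where the H1299 libraries were mixed the highest count was 0. Such splits keep the H1299 effect, some with its sign reversed, and A549 was regrouped in most and intact in others, where the effects of the lines add up. With the block, 5, 2 and 3 of 21 splits were as large as the real counts of 1712, 2797 and 1535 (highest other 4418, 3091 and 2123). Within each line 1 of 10 splits, the real one, was as large in all 6 comparisons (real 2625, 3680 and 1846 in H1299 and 1, 1 and 2 in A549, highest other 0), and 10 splits are too few for a share under 0.05.

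Log2 changes were smaller in A549 than in H1299, with slopes of A549 on H1299 of 0.183 (siYAP, over 4184 genes) and 0.192 (siTAZ, over 5241 genes), though these genes were called in H1299, which favours H1299. With the block they were 0.179 and 0.187, but each replicate number holds 1 library of every group, so an offset shared by a number cancels from these changes by design, leaving replicate batches untested. Less complete knockdown may contribute: the H1299 siTAZ library with the most WWTR1 left, 32.0%, had a slope of 0.596 on the other H1299 siTAZ libraries, and the A549 siTAZ libraries with 28.9% to 39.7% left had 0.139 to 0.185, but a single library cannot tell. Nor can the cell line be told apart from medium and experiment.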

How the results depend on the processing

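YAP1 and WWTR1 kept the direction and the call of their knockdown under every alternative, with log2 changes from -2.73 to -2.33 and -2.97 to -2.09 in H1299 and from -1.87 to -1.67 and -1.79 to -1.53 in A549 when a library was left out. All 50 genes named in H1299 did so under each setting, as did 296 of 300 values with a library left out. Of 50 named with the block in A549, 142 of 150 such values kept their call. Of members named with lists and called, 867 of 1074 such values in H1299 and 385 of 528 in A549 with the block kept the call, and none reversed. Other settings kept at least 171 of 179 of these calls in H1299. With the same block in A549, DESeq2 kept 139 of 171, limma-voom 160 of 176 and robust shrinkage 172 of 176. Of the 29 line differences, 139 of 348 did, and limma-voom kept 21.

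Where a count moved, the cause was not tested, except for stricter thresholds, which call fewer genes by construction. With the block, edgeR called 4461, 5606 and 3399 genes in H1299 (siYAP, siTAZ, siYAP against siTAZ), 909, 2134 and 1127 in A549 and 1712, 2797 and 1535 in the joint fit. A 1.5-fold minimum left 1112, 1537 and 807 in H1299. An adjusted p below 0.01 left 940, 1600 and 717 in H1299 and 0, 0 and 0 in the joint fit. DESeq2 called 6, 52 and 19 in A549 and 130, 314 and 258 in the joint fit, and limma-voom called 2 for A549 siTAZ. Combinations with the block were chosen after seeing the data. In A549 with the block, DESeq2 called 363, 1160 and 518, limma-voom 591 for siYAP, a 1.5-fold minimum 56, 192 and 96, and an adjusted p below 0.01 left 368, 1221 and 563. With at least 5 CPM, the correlation between lines for siYAP against siTAZ was 0.421 in place of 0.274.

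With 1 library left out, the counts ranged from 1124 to 3066, 1715 to 4301 and 856 to 2006 in H1299, from 1 to 2 for A549 siTAZ, and from 0 to 130, 1 to 254 and 3 to 138 in the joint fit. With a replicate number left out, they ranged in A549 with the block from 157 to 739, 940 to 1593 and 289 to 703.

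Of 49 list calls against control, 0 were kept by camera with an estimated correlation, with or without the block. Fry kept 12 of them and called 2 other lists (14 in all). Of 10 calls between siYAP and siTAZ, an estimated correlation kept 0, with or without the block, fry called 0 and the block 20, and leaving out a library gave 10 to 19. The calls thus hold only with the preset 0.01, save the 12 kept by fry. In H1299 the block lost no gene named, and of 64 members named with lists but not called it called 24.

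In A549 without the block, some lists reversed when a library was left out (camera adjusted p of the reversed direction, then lowest to highest). For siYAP these were mitosis (0.591, 2.17e-18 to 0.756), recombination (0.56, 2.53e-09 to 0.56) and p53 (0.0229, 0.0198 to 0.881) without siYAP 3. Cholesterol reversed without siControl 1 (0.00449, 3.75e-05 to 0.714). For siTAZ mitosis did without siControl 2 (0.786) or siTAZ 3 (0.153, 9.08e-13 to 0.786), and cholesterol without siTAZ 1 (0.0488, 0.000125 to 0.756). Recombination (0.966, 8.24e-09 to 0.966), remodelling (0.879, 0.00073 to 0.879) and interferon (0.331, 0.00031 to 0.331) did so without siTAZ 3. For siYAP against siTAZ mitosis did without siYAP 3 (0.00056) or siTAZ 2 (0.00362, 1.43e-07 to 0.757). Replication (0.00053, 9.78e-06 to 0.755), recombination (0.00751, 0.000148 to 0.744) and interferon (0.00751, 0.000183 to 0.642) did so without siTAZ 3. With the block, where whole replicate numbers were left out, 0 of 216 list values reversed. The cause was not tested.

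On its own simulated data the fit without the block found 25.4% of genes changed 1.5-fold in A549 and 53.2% in H1299. The block's own effect was not tested there.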

Other observations

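The test of incomplete knockdown in H1299 replicate 2 was chosen only after the result was seen, and the added settings of the word test were chosen after its first result.

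In H1299, replicate 2 responded less to both siRNAs: its slope on the other replicates was 0.508 for siYAP and 0.596 for siTAZ, against 1.27 and 1.11 for replicates 1 and 3 of siYAP and 1.13 and 1.18 of siTAZ. The targeted transcript left in replicate 2 was 23.9% for siYAP (15.5% and 14.3% in replicates 1 and 3) and 32.0% for siTAZ (13.9% and 11.2%). Less complete knockdown may contribute. Against controls 1 and 3 alone the slopes were 0.657 and 0.796, but 1 library per siRNA cannot exclude an atypical control. No biological explanation was tested.

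A set of 39 genes was lower under siYAP than under both siControl and siTAZ and not called under siTAZ, in both lines with the block, where independent lists would share 2.81, among them ARL6IP1, COMMD8, PEX2, TNFRSF21, MCL1 and E2F5 (chosen after their values were seen). An siRNA can lower transcripts whose 3′ UTR matches its seed, so words of 7 bases in 3′ UTRs were ranked by their tie to lower expression in 11686 genes. The word most tied in H1299 siYAP, TTCTTAA (t = -6.84), ranked 8 among all such words in A549 siYAP and 11028 and 7474 under siTAZ, and 6 in A549 without the block. Without the set's genes, chosen as lower in both lines, it ranked 16, and with mean expression in the model the top word CTTCTTA ranked 13. Of the set's 38 genes with a UTR 24 carried TTCTTAA against 13.5 expected (ratio 1.78). The planned limits, a rank in the first 10 and a ratio above 1.5, were met, but word and set were both chosen by H1299 siYAP, and 16 and 13 lie outside. GAGAGGA, chosen after its ranks were seen, ranked 3 in H1299 siYAP, 1 in A549 siYAP (t = -6.40) and 12406 and 7677 under siTAZ, and 4 and 1 under siYAP without the set's genes. Off-target effects of the pool stay open. Loss of YAP cannot be told apart from the pool with 1 pool per gene, and the siRNA sequences are not in the sources.

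Under siTAZ the top word in H1299, AGCTACT (t = -6.29), ranked 2 in A549, and 104 (t = -3.11) and 930 under siYAP. ATCACTA, chosen by its ranks, ranked 10 and 3 under siTAZ and 16094 and 10407 under siYAP. By the same 3 tests for siTAZ alone with the block, 54 genes were lower in both lines (9.2 expected) and 71 higher (14.6). For siYAP alone 1 was higher (1.01), ZBED5-AS1.

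In H1299, 51 genes went in opposite directions under siYAP and siTAZ (63 and 114 with the block), among them TGFBI (-1.57 and 1.15), MMP10 (-0.89 and 1.25) and CDKN2B (-1.02 and 0.45), chosen after their values were seen. Single libraries stood out for some genes, chosen likewise. H1299 siYAP replicate 1 held 78.9 CPM of the metallothionein MT1X (1.24 to 6.75 in the other libraries), 397 CPM of MT2A (51.5 to 112.5) and 266 CPM of the zinc exporter SLC30A1 (12.6 to 61.8). BCYRN1, a small neuronal RNA gene, stood at 34.9 and 45.8 CPM in H1299 siYAP replicates 1 and 2, 1.00 CPM in replicate 3 and 0.35 to 0.68 CPM in the other H1299 libraries. In siYAP against siControl these gave log2 changes of 3.95 ± 1.14 (MT1X, adjusted p = 0.0308), 1.17 ± 0.54 (MT2A, 0.151), 2.90 ± 0.82 (SLC30A1, 0.0281) and 5.60 ± 1.00 (BCYRN1, 0.0032).

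The authors' deposited table of differential expression called 2651 genes for H1299 siYAP, 3565 for siTAZ and 1902 for siYAP against siTAZ, and that for A549 278, 966 and 468. Refitting all genes of the tables with DESeq2, with no filter, called 2653, 3565 and 1903 in H1299 without a block, and 278, 966 and 468 in A549 with the replicate block. The other DESeq2 counts are from fits to the genes that passed the filter, with independent filtering.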
